A study of Rattus norvegicus with 13 samples.

How the data were processed

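Gene expression was measured on 13 Agilent rat microarrays of 1 colour. They held mammary carcinomas of female Sprague-Dawley rats irradiated at 3 weeks of age (IR-3W, 4 arrays) or at 7 weeks of age (IR-7W, 6 arrays), and normal mammary tissue of non-irradiated rats (normal, 3 arrays). Groups and replicate numbers were taken from the sample titles.

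Each array file held Feature Extraction scanner output, version 10.7.3.1 per the file headers. The authors' deposited intensity per spot was the processed green signal, a linear fluorescence intensity after background subtraction per the file headers. The arrays carried Cy3 alone per the labels, and the files held no red channel. The labels' description of a channel 2 stands for the mean of the 3 normal samples, and no second RNA was hybridised per the file headers. A separate deposited table held log2 values, whose scale and centring the sources used here do not state. Set against the scanner values, between 99.6 and 99.8% of its values per array lay within 0.01 of the log2 signal minus the array's 75th percentile minus the mean of the 3 normal arrays. Between 29.4 and 52.2% of its entries per array were blank, its columns had medians from -0.20 to 0.05, and it served only as an alternative.

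Of 45018 spots per array, 1639 were controls and 43379 were not, and these held 41012 probes, of which 263 were spotted more than once. Control spots and spots marked as outliers by the scanner software were left out, and saturated spots were kept. The log2 of the processed signal was taken, each array's 75th percentile over the spots that were not controls was subtracted, and spots of the same probe were averaged. A probe was kept where it was well above background on at least 3 arrays, which left 29307 probes. RefSeq accessions stood beside 20503 probes, and 16815 probes were matched to a gene symbol of the RefSeq table of assembly GRCr8, matched without accession versions, while 24197 had no match and 0 matched several genes. Of several probes of a gene (2437 genes), the probe with the highest mean log2 signal was used. This gave 25361 features, called genes throughout, of which 10516 had a symbol. A missing value on an array was found in 498 of them. Genes were tested wherever the values allowed, 25360 against normal tissue. Coordinates are not given, because the array's genome build differed from that of the gene table.

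All 13 arrays were fitted in a single model with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table, version 1.17.8, for reading. The 3 contrasts were IR-3W carcinoma minus normal, IR-7W carcinoma minus normal, and IR-3W minus IR-7W carcinoma. Two-sided p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold, and log2 differences are given with their standard error (SE). The labels do not say whether arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. For the carcinoma groups, the score of a list (the mean over its genes of the log2 value minus that gene's mean over all arrays) was compared by an exact two-sided permutation test over 210 splits, whose smallest possible p is 0.00476. A gene not well above background on any array of a group has only a bound there. It is then given as "at least N-fold", from the brighter group's mean against a floor made on each array from the higher of the dimmest signal called well above background and the gene's own signal. The bound covers the detection floor and not the spread between samples. The number of arrays limits the precision.

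The design, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The rule took, per contrast, the 12 highest and 12 lowest passing genes with a symbol and no overlap between the groups' arrays, in each list up to 4 members with the smallest p, and in every contrast Esr1, Pgr, Prlr, the ErbB ligands and Egfr, Erbb2, Erbb3 and Erbb4 where measured. Btc, Epgn, Nrg3, Nrg4 and Erbb4 were not tested here. The text names part of these, and some genes are not reported here. The 3 lists of hormone receptors, ErbB ligands and mammary development regulators were informed by knowledge of the study's topic. The other lists covered mammary and other cell types that the tissue could hold and the pathways named in the text, each needing 5 tested members for a list test, which 29 of the 30 had.

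The same steps were tested on simulated data, with 24863 genes on which 50 genes were changed per size. At log2 differences of 1, 2, 3 and 4, limma recovered 14, 52, 78 and 94% for IR-3W against normal, 14, 60, 82 and 96% for IR-7W against normal, and 30, 66, 88 and 96% between the carcinoma groups. Of 24633 unchanged genes it called 9, 12 and 8. The noise of each gene was drawn independently, so these counts do not cover structure that genes share across real samples.

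Alternatives were normexp background correction of the median signals (offset 50), quantile scaling, scaling by the median of probes well above background, the deposited log2 values, no filter on dim probes, a filter asking for all arrays, outlier spots kept, the mean of a gene's probes, a fit of only the 2 groups compared, array weights, a trended robust variance, the replicate number as a block, the slide as a block or random block, the slide with both carcinoma groups alone, an adjusted p under 0.01, and each array left out. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.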

Results

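The study varied the age at irradiation relative to puberty. Female rats of the Sprague-Dawley stock, an outbred strain prone to mammary tumours, received 2 Gy of caesium gamma rays to the whole body at 0.6 Gy per minute, either before puberty (3 weeks) or after it (7 weeks). From week 9 they were given a diet with 23.5% corn oil, and palpable carcinomas were collected at 50 weeks. The labels describe the normal tissue in 1 place as matched in age and in another as coming from rats of 7 weeks, so the age of the normal group relative to the carcinomas is not settled. The diet is given for the carcinoma groups alone, so a difference in diet from the normal group is not settled either. Expression was measured in 4 IR-3W carcinomas, 6 IR-7W carcinomas and 3 normal mammary tissues, 1 array each.

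Normal arrays were dimmer than carcinoma arrays. The 75th percentile of the signal was 82.3 to 179 on the normal arrays and 276 to 1242 on the carcinoma arrays, and 48.7 to 54.2% of spots were well above background against 58.0 to 71.0%. Before scaling, the 10 spike-in controls, synthetic RNAs added at known amounts, were 0.72 to 3.51 log2 higher on the carcinoma arrays than on the normal arrays. The slope of their log signal on log amount, per the file headers, was 0.759 to 0.845 against 0.924 to 0.987. Pairs of arrays correlated across genes, which are not independent replicates, at r from 0.963 to 0.976 within normal, 0.879 to 0.961 within IR-3W and 0.927 to 0.967 within IR-7W. Slide 4 held the 3 normal arrays and was read in scan 2, on another scanner per the file headers. Scan 1 held all carcinoma arrays, with IR-7W 2, 3, 4 and 6 on slide 1, IR-3W 1 and 2 with IR-7W 1 and 5 on slide 2, and IR-3W 3 and 4 on slide 3. Scan and group cannot be told apart for any comparison with normal tissue, while slide 2 allows the carcinoma groups to be compared within a slide.

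**Figure D1:**
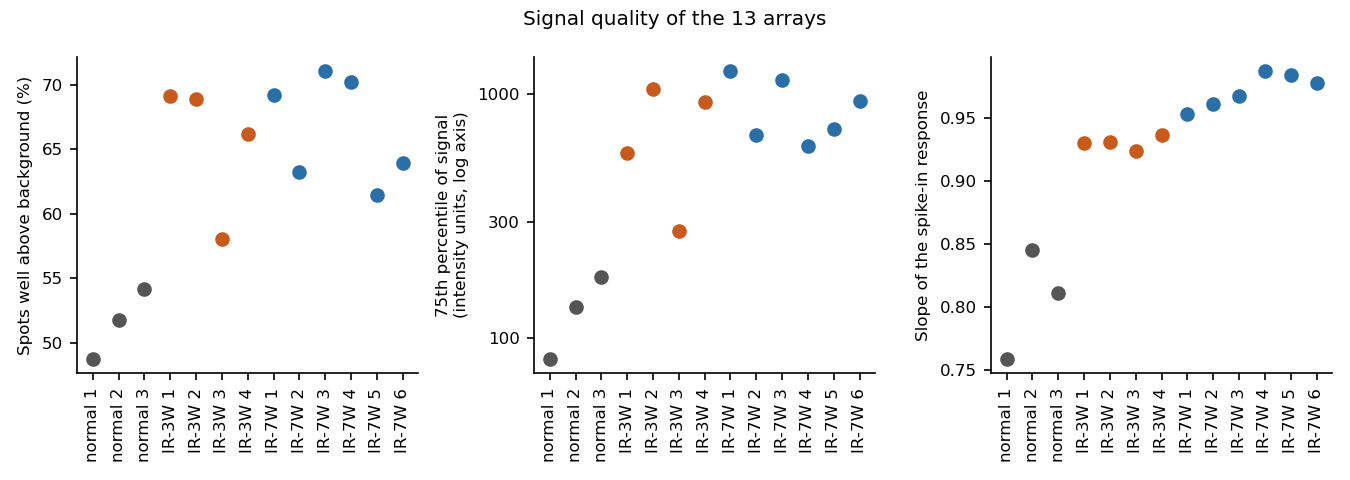
Percent of spots well above background, 75th percentile of the signal (intensity, log axis) and slope of the spike-in response (log signal per log amount), with 1 point per array and arrays grouped as normal, IR-3W and IR-7W. Normal arrays lie at 48.7 to 54.2% and carcinoma arrays at 58.0 to 71.0%.

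IR-3W carcinomas were compared with normal tissue to ask which genes distinguish tumours after prepubertal irradiation. Of 22 adipocyte markers 17 fell, and of 30 matrix genes 8 rose and 22 did not pass. Adipoq, which encodes the fat-cell hormone adiponectin, fell by 10.27 ± 1.02 on the log2 scale (SE), from 5.23 ± 0.31 (SD, n = 3) to -5.04 ± 1.05 (SD, n = 4), with an adjusted p of 4.66e-05 in limma. Pck1, the rate-limiting enzyme of gluconeogenesis and of glycerol formation in fat, fell by 6.40 ± 0.27. Col1a1, a chain of type I collagen, rose by 2.34 ± 0.42, from 4.85 ± 0.09 to 7.19 ± 0.90 (adjusted p = 0.00267), and Lum, which encodes the matrix proteoglycan lumican, rose by 3.97 ± 0.66. All 4 carcinomas lay beyond all 3 normal samples for each of these genes. Adipoq and Pck1 were well above background on 3 of 4 IR-3W arrays.

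Of 22 adipocyte markers tested, 17 fell and 0 rose, and 18 fell when adjusted over the list alone. The list had a median of -3.20 and an adjusted p of 1.18e-14 in camera (adjusted p = 0.0225 with an estimated correlation). Cidec, a lipid droplet protein, fell by 6.51 ± 0.94 and Cfd, the adipocyte-secreted protease adipsin, fell by 3.21 ± 0.48. Of 22 fatty acid and lipid synthesis genes, 1 rose and 5 fell (2 and 7 adjusted over the list alone), without a shift of the list (adjusted p = 0.103). Among them Scd, which makes monounsaturated fatty acids, fell by 5.22 ± 0.98 and Dgat2, which completes triglyceride synthesis, fell by 3.18 ± 0.64. Among the lowest genes, Abcd2, a peroxisomal fatty acid transporter, was at least 140-fold lower and Cpa1, a pancreatic-type carboxypeptidase, at least 119-fold lower, while normexp gave smaller fitted differences of -3.55 and -3.39.

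Of 30 fibroblast and extracellular matrix genes, 8 rose and 0 fell, and 14 rose when adjusted over the list alone, with a median of 1.20 (adjusted p = 0.000128; adjusted p = 0.79 with an estimated correlation and 0.108 with fry). Col1a2, the partner chain of type I collagen, rose by 2.70 ± 0.46 and Postn, the matricellular protein periostin, rose by 2.87 ± 0.58. Of 23 hypoxia and glycolysis genes, 3 rose and 0 fell, as when adjusted over the list alone (median 0.91, adjusted p = 0.0239; adjusted p = 0.993 with an estimated correlation). The list call was lost without normal 3 (adjusted p = 0.0999) and without IR-3W 2 (adjusted p = 0.503). Car9, the hypoxia-induced carbonic anhydrase, was at least 7.91-fold higher, a call lost under normexp (adjusted p = 0.165), and P4ha2, a collagen prolyl hydroxylase, rose by 2.31 ± 0.38. Of 44 cell cycle genes, 2 rose, and 0 were called by limma when adjusted over the list alone (7 at an unadjusted p under 0.05). That list had a median of 0.94 (adjusted p = 0.000998; adjusted p = 0.993 with an estimated correlation), and its call was lost without normal 2 (adjusted p = 0.144) and without IR-3W 2 (adjusted p = 0.151).

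Interferon, endothelial and T and NK cell lists passed camera downward in IR-3W carcinomas, but not with an estimated correlation or with fry, and few single genes passed. Of 27 interferon response genes, 2 fell, as when adjusted over the list alone (median -0.66, adjusted p = 0.00601; adjusted p = 0.79 with an estimated correlation). These were Psmb8, an immunoproteasome subunit, with -0.97 ± 0.22, lost without normal 1 (adjusted p = 0.0546), and Rsad2, the antiviral protein viperin, with -1.81 ± 0.44, lost without normal 1 (adjusted p = 0.06) and normal 2 (adjusted p = 0.061). Of 16 endothelial markers, 2 fell, also adjusted over the list alone (median -0.94, adjusted p = 0.00842; adjusted p = 0.79 with an estimated correlation), and the list call was lost without IR-3W 1 (adjusted p = 0.0656). Of 23 T and NK cell markers, 1 fell, also adjusted over the list alone (median -0.87, adjusted p = 0.0239; adjusted p = 0.79 with an estimated correlation). This list call was lost without normal 2 (adjusted p = 0.1), IR-3W 2 (adjusted p = 0.163) and IR-3W 3 (adjusted p = 0.0674).

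Epithelial and signalling genes gave single calls without list shifts. Spint2, a membrane-bound protease inhibitor of epithelia, rose by 3.83 ± 0.35, from -1.77 ± 0.71 to 2.06 ± 0.54, and Cldn9, a tight junction claudin, rose by 4.29 ± 0.63. Notch3, a Notch receptor, rose by 3.79 ± 0.47, and Wnt5a, a non-canonical Wnt ligand, was at least 4.74-fold higher, a call lost under normexp (adjusted p = 0.231). Ghr, the growth hormone receptor, fell by 3.89 ± 0.41, from 2.59 ± 0.20 to -1.30 ± 0.61 (adjusted p = 7.65e-05), in tissue whose adipocyte list also fell. Cnn1, a contractile protein of myoepithelial cells, fell by 2.35 ± 0.52, a call lost in a fit of only the 2 groups (adjusted p = 0.0757). Esr1 (adjusted p = 0.351; 0.00573 with array weights), the oestrogen receptor, which was not well above background on any normal or IR-3W array, Prlr (-0.39 ± 0.68, adjusted p = 0.748), the prolactin receptor, and Areg (1.28 ± 0.58, adjusted p = 0.162), the ErbB ligand amphiregulin, did not pass. Neither did Egfr (-0.87), Erbb2 (-0.25, adjusted p = 0.0278 with array weights), Tgfa (0.84, adjusted p = 0.0435 without IR-3W 3), Nrg2 (1.43, adjusted p = 0.0286 with array weights) or Erbb3 (0.18, and -0.23 under normexp, where the median of all genes moved to -0.21). Pgr, the progesterone receptor, was not well above background on any normal array and did not pass (adjusted p = 0.573).

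Across all genes, 3700 passed in limma, 2342 higher and 1358 lower, of which 3217 also differed at least 2-fold and 1465 had a symbol. The count was 2265 without normal 1, 2101 without normal 2 and 4541 with the slide as a random block. That fit took a correlation of -0.0581 between arrays of a slide. All normal arrays lay on a slide of their own, so it does not remove a slide effect. Lower genes outnumbered higher ones without the filter on dim probes (2762 higher, 8298 lower) and with the filter on all arrays (1257 and 1359), array weights gave 4895 and 4791, and normexp reduced Adipoq to -6.63, Cidec to -4.10 and Cnn1 to -1.31.

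IR-7W carcinomas were set against the same normal tissue to ask the same of tumours after postpubertal irradiation. Areg rose, and 17 of 22 adipocyte and 11 of 16 endothelial markers fell. Areg, which encodes an ErbB ligand induced by oestrogen in mammary epithelium, rose by 4.07 ± 0.54 on the log2 scale, from 2.73 ± 0.50 (SD, n = 3) to 6.80 ± 0.68 (SD, n = 6), with an adjusted p of 0.000237 in limma. Adipoq fell by 9.69 ± 0.95 and Pparg, the master regulator of fat-cell differentiation, fell by 4.55 ± 0.54, from 0.92 ± 0.23 to -3.64 ± 0.52. Sox17, an endothelial transcription factor, fell by 3.35 ± 0.64 (adjusted p = 0.0029). All 6 carcinomas lay beyond all 3 normal samples for these 4 genes. Adipoq was well above background on 4 of 6 IR-7W arrays and Sox17 on 5.

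Of 22 adipocyte markers, 17 fell and 0 rose, and 18 fell when adjusted over the list alone (median -3.01, adjusted p = 1.91e-12; adjusted p = 0.04 with an estimated correlation). Fabp4, the fatty acid carrier of fat cells, fell by 6.44 ± 0.96 and Cfd fell by 4.41 ± 0.44. Of the 22 lipid synthesis genes, 1 rose and 4 fell, as when adjusted over the list alone (adjusted p of the list = 0.127), among them Scd with -4.48 ± 0.91. Of 16 endothelial markers, 11 fell and 0 rose, and 13 fell when adjusted over the list alone (median -1.85, adjusted p = 5.38e-06; adjusted p = 0.858 with an estimated correlation). Emcn, an endothelial surface sialomucin, fell by 2.12 ± 0.39 and Tek, the angiopoietin receptor, well above background on 4 of 6 IR-7W arrays, fell by 2.12 ± 0.46.

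Several stromal and myeloid genes fell while their lists did not pass. Of 30 fibroblast and matrix genes, 3 rose and 7 fell (3 and 9 adjusted over the list alone; adjusted p of the list = 0.0796). Ogn, the small proteoglycan osteoglycin, fell by 3.21 ± 0.50, Mfap5, a microfibril protein, fell by 2.67 ± 0.51, and Pdgfra, a PDGF receptor of fibroblasts, fell by 1.65 ± 0.30. Of 24 macrophage and myeloid markers, 0 rose and 6 fell, 7 when adjusted over the list alone (adjusted p of the list = 0.0549). Fcer1g, a signalling chain of Fc receptors, fell by 2.67 ± 0.39 and Tyrobp, an adaptor of myeloid receptors, fell by 1.67 ± 0.37. Of 15 growth hormone and IGF axis genes, 1 rose and 4 fell, as when adjusted over the list alone (adjusted p of the list = 0.35; 0.046 with fry). Ghr fell by 3.68 ± 0.38 and Igf1, the growth factor made by stroma in response to growth hormone, fell from 6.16 ± 0.15 to 3.76 ± 0.45 (adjusted p = 0.00221), where the adipocyte list fell as well.

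Hormone-related genes went both ways. Of 10 hormone receptors tested, 2 rose and 2 fell, as when adjusted over the list alone (adjusted p of the list = 0.944). Those that fell were Ghr and Vdr, the vitamin D receptor, at -1.86 ± 0.56 (adjusted p = 0.0339), whose call was lost without normal 1 (0.151), normal 2 (0.139) or any of IR-7W 1 to 5 (0.0503 to 0.0607). Prlr was higher by 2.49 ± 0.63, 0.90 ± 0.47 against -1.59 ± 0.24 (adjusted p = 0.0148), and its call was lost without normal 1 (adjusted p = 0.0615) or normal 3 (adjusted p = 0.0506). Pgr was at least 3.45-fold higher (adjusted p = 0.0106), a call lost without normal 3 (adjusted p = 0.0611), under normexp (adjusted p = 0.97) and with deposited values. Esr1 was not well above background on any normal array and did not pass (adjusted p = 0.261). Cited1, a cofactor of oestrogen receptor in mammary epithelium, was higher by 5.75 ± 1.36 (adjusted p = 0.0104), lost without normal 2 (5.43, adjusted p = 0.0503). Tff3, an oestrogen-responsive trefoil peptide, was at least 3.16-fold lower. Of 20 oestrogen and progesterone responsive genes, 5 rose and 3 fell (6 and 6 adjusted over the list alone). That list did not pass (adjusted p = 0.944), with a median of -0.04, a mean of 0.40 and a downward camera direction.

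Of 7 ErbB ligands tested, Areg alone passed, while adjusted over the list alone 3 passed upward and 1 downward (adjusted p of the list = 0.192; 0.00386 with fry). Ereg, the ligand epiregulin, was not well above background on any normal array and did not pass (adjusted p = 0.0851; 0.0126 with array weights, and 0.992 under normexp). The difference was 1.53 ± 0.53 for Nrg2 and -1.56 ± 0.56 for Hbegf, neither of which passed, though 7 other settings passed Nrg2 (adjusted p down to 0.00384) and 6 passed Hbegf (down to 0.00317). Of 9 ErbB receptors and feedback regulators, 2 passed upward, as when adjusted over the list alone (adjusted p of the list = 0.262). Erbb3, the neuregulin receptor, well above background on 2 of 3 normal arrays, stood at 1.17 ± 0.34 (adjusted p = 0.029). It stood at -0.07 under normexp, where the median of all genes moved to -0.55, and lost its call without normal 1 (adjusted p = 0.113), normal 3 (adjusted p = 0.131), IR-7W 1 (adjusted p = 0.0537), IR-7W 3 (adjusted p = 0.0566) or IR-7W 6 (adjusted p = 0.0528). Erbb2 (0.08 ± 0.22; -0.03 with array weights) and Egfr (-0.64 ± 0.47) did not pass.

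Of 40 mammary development regulators, 8 rose and 5 fell (10 and 8 adjusted over the list alone; adjusted p of the list = 0.824). Tbx3, a transcription factor required for mammary placodes, rose by 3.41 ± 0.57, from -1.15 ± 0.07 to 2.26 ± 0.78, and Msx2, a homeobox factor of mammary bud development, was at least 6.97-fold higher, a call lost under normexp (adjusted p = 0.102) and with deposited values. Notch3 rose by 3.55 ± 0.40. Among the highest genes, Upk3a, a urothelial membrane protein, passed upward (adjusted p = 0.00458), but only 1 of 3 normal arrays was well above background, so no size is given. Capn8, a stomach calpain, well above background on 2 of 3 normal arrays, rose by 5.28 ± 0.70, and Cdkn2a, which encodes cell cycle inhibitors, by 4.89 (adjusted p = 0.00455). In limma 5274 genes passed, 3029 higher and 2245 lower, of which 4308 differed at least 2-fold and 2156 had a symbol. The count was 3041 without normal 1, 3055 without normal 2 and 6496 with the slide as a random block, which again took the correlation of -0.0581. Higher and lower genes numbered 2064 and 10662 under normexp, 3426 and 10347 without the filter on dim probes, 1585 and 1996 with the filter on all arrays and 5312 and 5323 with array weights, and normexp reduced Sox17 to -2.10 and Cdkn2a to 3.26.

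For IR-7W against normal tissue the other lists had these values, and whether the carcinoma groups differ is tested directly further on. Adjusted p was 0.0549 for cell cycle genes, with 2 rising (0 by limma adjusted over the list alone, 6 at an unadjusted p under 0.05). It was 0.127 for interferon response genes (2 fell) and 0.6 for hypoxia and glycolysis genes (2 rose), with the same counts adjusted over the list alone. T and NK cell markers had 0.0981, with 0 called by limma, also adjusted over the list alone (3 at an unadjusted p under 0.05).

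Lists that passed in neither comparison with normal tissue had these adjusted p-values, IR-3W first. Luminal and general epithelial markers had 0.793 and 0.0586, with 1 and 2 of 27 rising (1 and 1 adjusted over the list alone). Myoepithelial and basal markers had 0.217, with 2 rising and 4 falling of 20 (3 and 5 adjusted over the list alone), and 0.944, with 2 rising and 1 falling (1 and 0; median -0.01, mean 0.14). B and plasma cell markers had 0.126 and 0.0549, with 1 and 2 of 6 falling (1 and 4 adjusted over the list alone), and lymph node stroma had 0.172 and 0.127, with 0 and 1 of 5 falling in limma (2 and 1 adjusted over the list alone, 2 at an unadjusted p under 0.05 for IR-3W). Milk protein and secretory genes had 0.163 and 0.124, with 0 of 20 called by limma in either, also adjusted over the list alone (2 and 4 at an unadjusted p under 0.05). Red blood cell markers had 0.981 and 0.288, with 1 of 6 rising in each (1 up and 1 down, then 3 up and 1 down, adjusted over the list alone; median 0.23 and mean -0.05 for IR-3W).

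For IR-3W the remaining lists did not pass either. Macrophage and myeloid markers had an adjusted p of 0.776, with 1 rising and 1 falling (0 by limma adjusted over the list alone, 5 at an unadjusted p under 0.05), and ErbB ligands 0.496, with 0 of 7 called by limma, also adjusted over the list alone (2 at an unadjusted p under 0.05). ErbB receptors and feedback regulators had 0.981, with 1 rising (median -0.21, mean 0.20), hormone receptors 0.344, with 1 falling, and oestrogen and progesterone responsive genes 0.981, with 1 rising and 1 falling (median 0.16, mean -0.06), with the same counts adjusted over each list alone. Mammary development regulators had 0.793, with 6 rising and 1 falling (7 and 1 adjusted over the list alone), and the growth hormone and IGF axis 0.793, with 1 rising and 1 falling (1 and 2 adjusted over the list alone; median 0.06, camera direction downward).

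Both carcinoma groups shared many genes in their difference from normal tissue. Notch3, Spint2 and Sirt5, a mitochondrial deacylase, were higher in both, and Adipoq, Pck1, Cfd, Ghr and Scd were lower in both. Of 25360 genes, 1970 were higher and 907 lower in both, and 2 went opposite ways. Of these 2, named after their values were seen, 1 had no symbol and the other was Aspn, an inhibitor of TGF-beta signalling in matrix, with 1.82 ± 0.53 for IR-3W (adjusted p = 0.0351) and -1.68 ± 0.49 for IR-7W (adjusted p = 0.0284). Its calls were lost for IR-3W without any 1 normal or IR-3W array other than IR-3W 3 (adjusted p from 0.051 to 0.159) and for IR-7W without normal 1 (0.113) or normal 3 (0.11). Independent lists of these sizes would share 279.7 and 120.2, and 100 simulations of unchanged groups against the same normal samples shared 0 genes called by limma at most. These simulations drew the noise of each gene independently, while genes of real samples can vary together. Log2 differences correlated across genes at r = 0.83 (simulated 0.616), with a covariance of 1.01 (simulated 0.189). The difference of 0.824 between the covariances estimates what both comparisons share beyond the simulated noise of the shared controls. It includes any effect of the scan, since the simulations held none and scan and group cannot be told apart. Because 3 normal samples are too few to split, part of the excess in shared genes may come from the shared controls, and the shared count was 1740 without normal 1 and 1667 without normal 2.

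The 2 carcinoma groups were compared with each other to ask whether tumours differ by age at irradiation. Of 30 matrix genes 12 were higher in the IR-3W carcinomas and 18 did not pass, and Areg and Prlr were lower. With the slide as a block limma passed 0 genes (1072 at an unadjusted p under 0.05, no more than chance alone would give). Col3a1, the type III collagen chain, was higher by 2.90 ± 0.40 on the log2 scale (8.30 ± 0.81, SD, n = 4, against 5.41 ± 0.65, n = 6; adjusted p = 0.0149 in limma). Areg was at 4.01 ± 1.14 against 6.80 ± 0.68, a difference of -2.79 ± 0.49 (adjusted p = 0.0295). Prlr, through which prolactin drives alveolar growth, was at -1.98 ± 1.66 against 0.90 ± 0.47, a difference of -2.87 ± 0.57 (adjusted p = 0.0415). All 4 IR-3W values lay beyond all 6 IR-7W values for each of these genes.

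Of 30 fibroblast and extracellular matrix genes, 12 were higher and 0 lower, and 24 were higher when adjusted over the list alone (median 1.87, mean 1.69, adjusted p = 2.8e-26; adjusted p = 0.1 with an estimated correlation and 0.00276 with fry, which passed no other list here). With the slide as a block the mean was 1.10 (adjusted p = 4.8e-12). Ogn was higher by 3.44 ± 0.45 (3.11 within slide 2), Bgn, the proteoglycan biglycan, by 2.19 ± 0.31 (1.58 within slide 2), and Aspn, the collagen-binding proteoglycan asporin, by 3.50 ± 0.44 (3.39 within slide 2), while Col3a1 was higher by 1.77 within slide 2. These 4 genes passed with any 1 carcinoma array left out. So did Il24, a cytokine of the interleukin-10 family, at least 7.74-fold higher, Fgfbp1, a carrier that releases FGFs from matrix, at least 8.44-fold higher (fitted differences of 1.69 and 1.85 under normexp), a call lost in a fit of only the 2 groups, and Popdc2, a cyclic AMP-binding membrane protein of muscle, with -2.20 ± 0.33 (-1.65 within slide 2).

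Within slide 2 the difference was -2.49 for Areg and -2.63 for Prlr. Areg lost its call without IR-3W 2 (adjusted p = 0.0721), IR-3W 3 (0.0538), IR-3W 4 (0.117), IR-7W 2 (0.0535), IR-7W 3 (0.0622) or IR-7W 5 (0.0648), with differences from -2.50 to -2.89. Prlr passed only with all arrays or without IR-3W 1, and leaving out any other carcinoma array gave adjusted p from 0.0638 to 0.157 and differences from -2.38 to -2.99, and normexp gave -1.89. Over all other settings the adjusted p ranged from 0.00207 to 1 for Areg and from 0.00196 to 1 for Prlr. Pgr (-2.25 ± 0.64, adjusted p = 0.141) and Esr1 (adjusted p = 0.134) did not pass, with 2 of 4 IR-3W arrays well above background for Pgr and 0 for Esr1. The difference of Esr1 turned direction under normexp, also against the shifted median of all genes. Pgr and Esr1 both passed with array weights (adjusted p = 0.0113 and 0.00403), and Esr1 passed without IR-3W 3 (0.0391). The array weight was 0.229 for IR-3W 3 and 3.08 for IR-3W 4, so these calls of Esr1 are not separate. The 10 hormone receptors had 1 lower gene, 4 when adjusted over the list alone (median -0.28, mean -0.77, adjusted p = 0.0472; adjusted p = 0.397 with an estimated correlation). With the slide as a block their mean was -0.60 (adjusted p = 0.0498), while on slide 2 alone the call was lost (adjusted p = 0.0913). Under normexp the mean was 0.08, below the shifted median of all genes. The call was also lost without IR-3W 1 (0.0982), IR-3W 2 (0.056), IR-7W 1 (0.0843) or IR-7W 6 (0.0999). Among 7 ErbB ligands Areg alone passed, also adjusted over the list alone (adjusted p of the list = 0.357), beside Ereg with -2.02 (2 of 4 IR-3W arrays well above background), Hbegf with 1.14 (adjusted p = 0.0301 under normexp) and Tgfa with 0.09, or -0.10 under normexp.

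**Figure D2:**
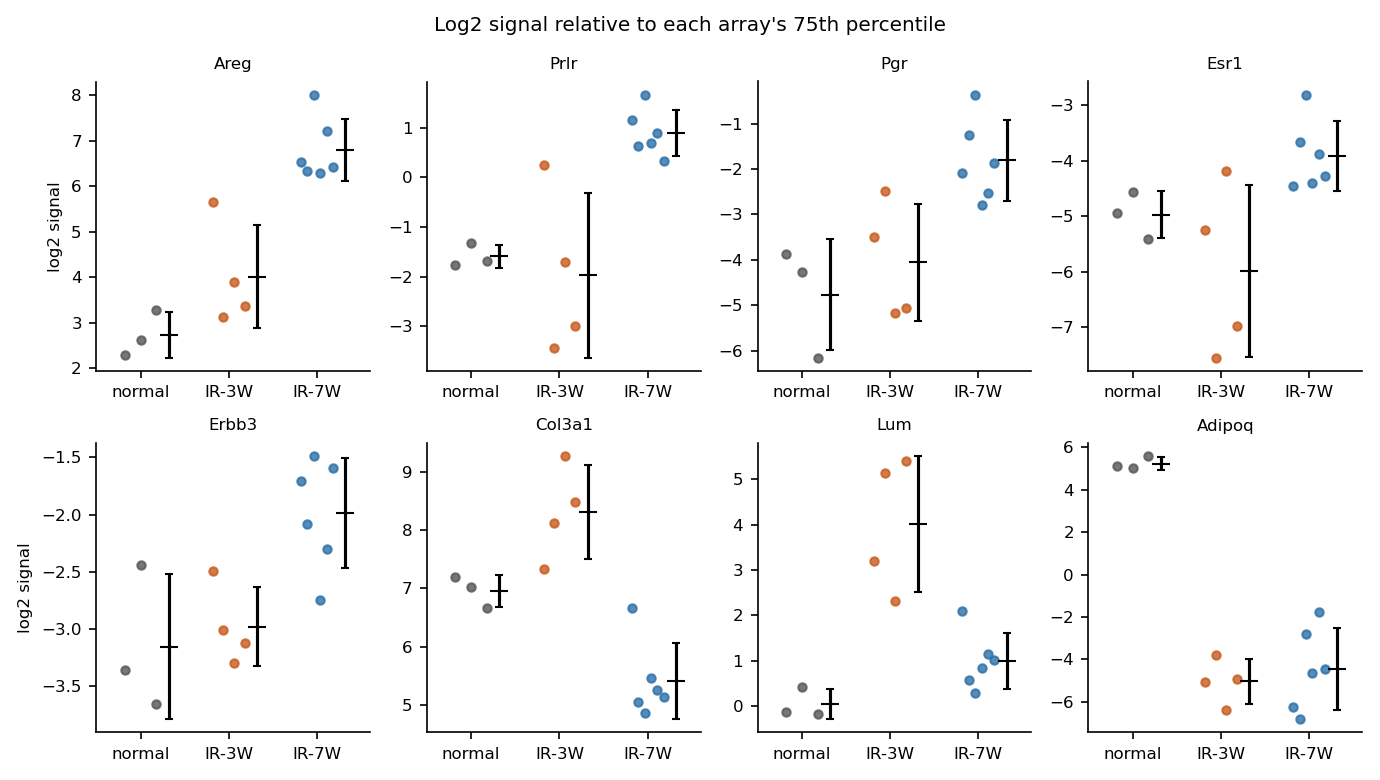
Log2 signal relative to each array's 75th percentile for 8 genes, with 1 point per array, and mean ± SD per group. Areg lay at 6.80 ± 0.68 in IR-7W and 4.01 ± 1.14 in IR-3W, and Col3a1 at 5.41 ± 0.65 and 8.30 ± 0.81, while Esr1 did not pass and its difference between the carcinoma groups turned direction under normexp.

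Of 27 luminal and general epithelial markers, 1 was lower, 3 when adjusted over the list alone (median -0.66, adjusted p = 3.29e-06; adjusted p = 0.397 with an estimated correlation), with a mean of -0.39 with the slide as a block (adjusted p = 1.78e-05). The 1 gene was Cldn3, a tight junction claudin of luminal cells, at -1.44 ± 0.28 (adjusted p = 0.0407), which passed only with all arrays or without IR-3W 1 or IR-7W 1 (adjusted p from 0.0666 to 0.15 otherwise). Of 20 myoepithelial and basal markers, 1 was lower, Cnn1 at -2.27, which passed only with all arrays or without IR-3W 1 or IR-3W 4 (adjusted p from 0.0563 to 0.0979 otherwise). The list (1 higher and 2 lower adjusted over the list alone) had a mean of -0.44 (adjusted p = 0.0247; adjusted p = 0.663 with an estimated correlation), and -0.18 with the slide block (adjusted p = 0.342). This call was lost without IR-3W 1 (0.216), IR-3W 3 (0.729) or IR-7W 1 (0.086).

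Of 24 macrophage and myeloid markers limma called 0, also adjusted over the list alone (7 at an unadjusted p under 0.05). The list mean was 0.71 (adjusted p = 0.000317; adjusted p = 0.663 with an estimated correlation), 1.06 with the slide block (adjusted p = 4.19e-06), and 0.25 without IR-3W 1 (adjusted p = 0.124). Of 23 hypoxia and glycolysis genes limma called 0, also adjusted over the list alone (4 at an unadjusted p under 0.05), and the mean was 0.58 (adjusted p = 0.000898; adjusted p = 0.663 with an estimated correlation), 0.84 with the slide block (adjusted p = 4.68e-05) and 0.15 without IR-3W 2 (adjusted p = 0.596). Under normexp this list did not pass camera (mean 0.40, just above the shifted median of all genes of 0.39, adjusted p = 0.932). The 16 endothelial markers had 0 limma calls, also adjusted over the list alone (5 at an unadjusted p under 0.05), and a mean of 0.76 (adjusted p = 0.000125; adjusted p = 0.663 with an estimated correlation), which did not hold within slides (0.03 with the slide block, adjusted p = 0.765).

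Lists near the threshold were ErbB receptors and feedback regulators (mean -0.45), interferon response genes (-0.20), red blood cell markers (-0.71) and cell cycle genes (0.32), each with an adjusted p of 0.0481 and 0 genes called by limma. At an unadjusted p under 0.05 there were 2, 9, 1 and 0 such genes, and adjusted over the list alone 0, 1, 0 and 0. With an estimated correlation the adjusted p was 0.663, 0.663, 0.663 and 0.977. With the slide as a block the means were -0.24 (adjusted p = 0.229), 0.12 (0.788), -1.36 (3.42e-05) and -0.28 (0.0149), so that interferon and cell cycle genes turned direction, and under normexp cell cycle genes did not pass (mean 0.33, below the shifted median of all genes, adjusted p = 0.77). Cell cycle genes stood at -0.07 without IR-3W 2. The ErbB receptor call was lost without IR-3W 1, IR-3W 3, IR-7W 1, IR-7W 3 or IR-7W 6 (adjusted p from 0.08 to 0.396), and the interferon call without IR-3W 1, 3 or 4 or IR-7W 1, 2, 4 or 6 (0.0622 to 0.339). The red blood cell call was lost without IR-3W 1, 2 or 3 or IR-7W 1 or 2 (0.094 to 0.338), and the cell cycle call without IR-3W 2 or 4 or IR-7W 2, 3, 4 or 6 (0.0753 to 0.649). With an estimated correlation 0 of 29 lists passed camera, and 3 had an unadjusted p under 0.05.

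The exact two-sided permutation test of scores passed 0 of 29 lists after adjustment, and 5 had an unadjusted p under 0.05. Matrix genes scored 1.08 ± 0.53 in IR-3W and -0.61 ± 0.45 in IR-7W, a difference of 1.69 (exact p = 0.00476, the smallest possible; adjusted p = 0.069). Oestrogen and progesterone responsive genes scored -0.22 ± 0.15 against 0.23 ± 0.14, a difference of -0.46 (exact p = 0.00476, adjusted p = 0.069), and -0.36 within slide 2. Of those 20 genes limma called 1 higher and 2 lower (3 and 4 adjusted over the list alone), with a median of 0.13 and an adjusted p of 0.914 in camera, whose direction was downward. Hormone receptors differed by -0.77 (exact p = 0.00952, adjusted p = 0.0921), luminal markers by -0.56 (exact p = 0.019, adjusted p = 0.138) and ErbB ligands by -0.59 (exact p = 0.0429, adjusted p = 0.249). Areg, Prlr and Pgr belong to the oestrogen and progesterone responsive genes. Prlr, Pgr and Esr1 belong to the hormone receptors, and Areg and Ereg to the ErbB ligands. The scores of these lists thus share genes already named and are not separate results.

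**Figure D3:**
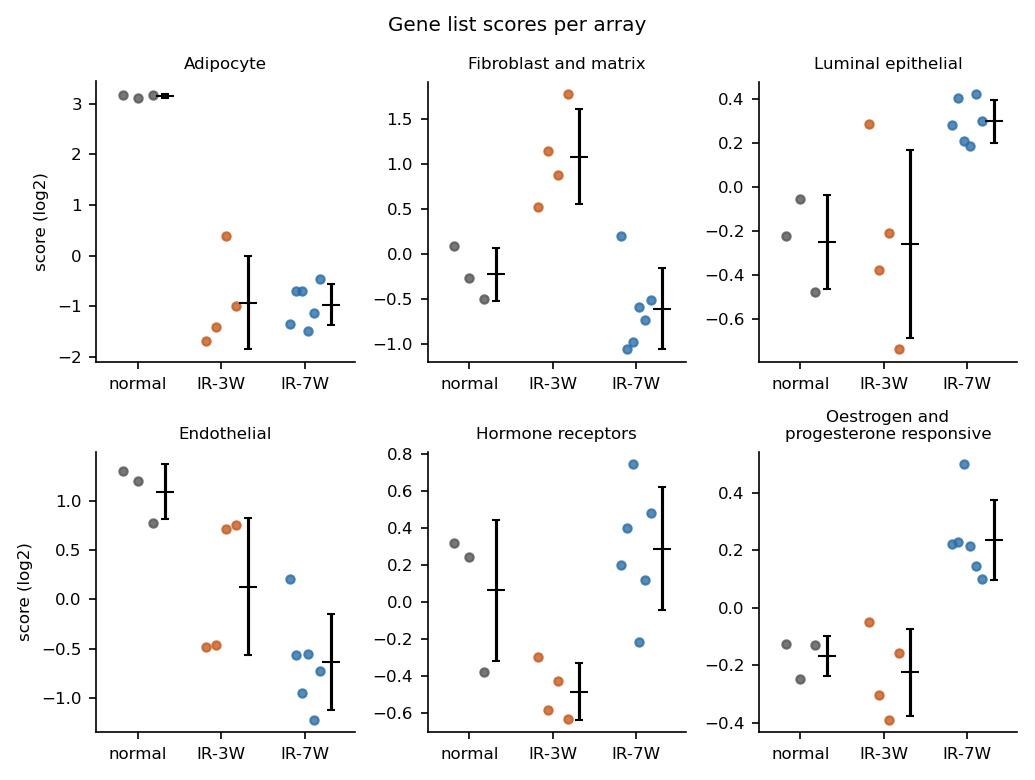
Scores of 6 gene lists (mean log2 value after each gene is centred over all arrays), with 1 point per array and mean ± SD per group. Matrix genes lay at 1.08 ± 0.53 in IR-3W and -0.61 ± 0.45 in IR-7W, and the endothelial difference between these groups was 0.03 with the slide as a block.

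Adjusted p between the carcinoma groups was 0.874 for adipocyte markers (median -0.27, mean 0.04), 0.761 for lipid synthesis genes, 0.483 for B and plasma cell markers, 0.511 for T and NK cell markers (median 0.01, mean -0.13), 0.913 for lymph node stroma and 0.894 for milk protein genes (mean -0.02, camera direction upward). Limma called 0 genes of these lists, also adjusted over each list alone, with 4, 1, 0, 2, 1 and 1 at an unadjusted p under 0.05. Adjusted p was 0.293 for the growth hormone and IGF axis, with 1 gene higher (2 adjusted over the list alone), Igfbp4, a binding protein that restrains IGFs, at 1.68 ± 0.33 and 0.83 within slide 2. Igfbp4 passed only with all arrays or without IR-3W 1 or IR-7W 1 (adjusted p from 0.0661 to 0.152 otherwise). Adjusted p was 0.996 for mammary development regulators, with 1 gene higher (5 higher and 5 lower adjusted over the list alone; median 0.09, mean -0.13).

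In limma 187 genes passed, 149 higher and 38 lower in IR-3W (6814 and 661 under normexp, 1072 and 609 with array weights, 305 and 278 without IR-3W 1), of which 184 differed at least 2-fold and 98 had a symbol. The count was 583 without IR-3W 1, 64 without IR-3W 2, 29 without IR-3W 4, and 63, 31, 114, 37 and 92 without IR-7W 2, 3, 4, 5 and 6.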

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

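The tests of the scan, of the epithelial share and of Areg and Prlr within the slide were chosen only after the result was seen. Areg and Prlr were lower in the IR-3W than in the IR-7W carcinomas (-2.79 and -2.87 log2). The mean of Areg and Prlr minus the luminal and epithelial score differed by -2.27 (1.28 ± 1.03, SD, n = 4, against 3.55 ± 0.58, n = 6), while that score itself differed by -0.56. Both genes were thus lower by more than these markers were on average. This does not decide whether a smaller share of epithelial cells was the whole cause, because the genes were chosen for their large differences. The slide as the cause stays open. On slide 2 the lowest IR-7W mean of both genes lay 0.891 above the highest IR-3W mean, but this decides nothing, because the genes were chosen for lying apart on all carcinoma arrays, these included. With the slide as a block neither passed, as the difference shrank and the SE grew (Areg from -2.79 ± 0.49 to -2.49 ± 0.79, adjusted p = 0.95; Prlr from -2.87 ± 0.57 to -2.63 ± 0.94, adjusted p = 1). A smaller share of hormone-sensing cells within the epithelium and age at irradiation stay open too, both untested.

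Between the carcinoma groups 187 genes differed, by the test of that difference itself. Of 100 splits drawn from 210, 4 gave as many, the real one included, and the highest other split gave 2528. A share so near the 0.05 set beforehand, from 100 splits, does not clearly exclude chance. That split set IR-3W 1 and 3 with IR-7W 4 and 5 against the rest, did not follow the slides, and points to a structure of the samples other than age at irradiation. Of 209 genes chosen at an unadjusted p under 0.001 in limma on the other slides, 87.6% had the same direction on slide 2, against 61.9% of all genes. Their median size was 1.23 there and 2.69 on the other slides. By the rule set beforehand this argues against the slide as the whole cause. The argument is weak, because slide 2 held 2 arrays of each group and genes can vary together. No chance level of this share was tested. A part that comes from the slides stays open, as does the untested structure of the tumours.

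Against normal tissue, 3700 genes differed for IR-3W and 5274 for IR-7W. A chance division of the arrays was argued against for both, since 1 of 35 and 1 of 84 splits, each the real one, gave as many. These are the smallest shares possible, and the highest other split gave 2703 and 2 genes. A scan difference would favour the real split as well, so the splits do not tell the cause. The 2703 came from moving IR-3W 3 to the normal samples, which points to a structure of the samples. Signal near background on the normal arrays, as the sole source of the number of passing genes, was argued against for IR-7W. Of the 15438 genes well above background on all arrays 20% passed (3085), against 20.8% of all genes. That share ignores direction. It also does not test a flatter response of the normal arrays to brighter signal, such as their lower spike-in slope. With the filter on all arrays lower genes outnumbered higher ones, so a part of dimness in the excess of higher genes stays open. Technical readings stay open, as scan and group cannot be told apart, since 0 scans held both. In 203 genes higher in IR-7W with another probe, the median ratio of that probe's log2 difference to the chosen probe's was 0.361 (75.9% in the same direction). It was 0.424 in 318 lower genes (71.7%). For IR-3W it was 0.22 in 160 higher genes (68.1%) and 0.551 in 200 lower genes (76.5%). In 20 genes between the carcinoma groups it was 0.956 (95%). Low ratios against normal tissue leave a probe-specific response of the separately scanned arrays open.

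Of 331 groups of samples examined, 15 held 1 sample far from the others, where chance alone gives about 1 in 20. In IR-3W 3, Aqp7 stood at -0.85 (others -7.41 to -7.28), Cyp4b1 at -0.21 (others -5.01 to -4.25), Fabp4 at 5.26 (others -0.15 to 0.29), Col1a1 at 8.52 (others 6.56 to 6.86) and Xrcc5 at -1.68 (others -0.91 to -0.82). In IR-3W 1, Tbx3 stood at 2.01 (others -0.58 to -0.16), Zmat3 at 2.16 (others 1.05 to 1.23) and Prkdc at -0.074 (others -0.82 to -0.70). In IR-3W 2, Nrg2 stood at 1.80 (others -0.91 to -0.47) and Fas at 0.43 (others 1.21 to 1.24). In IR-3W 4, Igfbp4 stood at 6.12 (others 5.13 to 5.29). In IR-7W 3, Igf1 stood at 2.90 (others 3.70 to 4.16) and the score of oestrogen and progesterone responsive genes at 0.50 (others 0.10 to 0.23). In IR-7W 1, Tmem182 stood at -4.39 (others -7.52 to -6.81) and Col3a1 at 6.67 (others 4.87 to 5.47).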

How the results depend on the processing

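The tests chosen only after the result was seen were normexp on the median signals, whose planned form on mean signals was not run because the files hold no such column, and the slide with both carcinoma groups alone. A random slide block was not run for list tests, which take none. Over all settings of the 217 gene and list results, 3988 values kept direction and side of the threshold, 590 lost the call, 41 gained one and 61 turned direction, counted against 0 for genes. Of the named genes that passed, the call held with each array left out in turn for 36 of 51 (IR-3W against normal), 49 of 73 (IR-7W against normal) and 7 of 28 (between carcinoma groups). In every setting it held for 24, 39 and 0, and the direction held for 49, 69 and 24. Signal over background limits genes dim on the normal arrays, which have only bounds. The median of all genes shifted under normexp by -0.21, -0.55 and 0.39 in the 3 comparisons (IR-3W against normal, IR-7W against normal, IR-3W against IR-7W), without a filter by -0.39 and -0.41 against normal, and with the filter on all arrays by -0.14 and -0.14. Changes under these settings are relative to those shifts. Except where a smaller number of samples, a stricter threshold or another number of genes tested shows it, the cause was not tested.

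For IR-3W against normal (3700), the gene count was 1188 with normexp, 11060 without the filter on dim probes, 1742 with only the 2 groups, 9686 with array weights, 1662 at an adjusted p under 0.01, and 2101 to 4987 with each array left out, lowest without normal 2 and 2265 without normal 1. For IR-7W against normal (5274) it was 12726, 13773 without the filter, 10635 with array weights, 2458 at an adjusted p under 0.01, and 3041 to 4810 with each array left out, lowest without normal 1 and 3055 without normal 2. For IR-3W against IR-7W (187) it was 7475 with normexp, 107 without the filter, 22 with only the 2 groups, 1681 with array weights, 334 with the slide as a random block, and 29 to 583 with each array left out (29 without IR-3W 4, 583 without IR-3W 1, 64 without IR-3W 2, and 63, 31, 114, 37 and 92 without IR-7W 2, 3, 4, 5 and 6). In limma it was 0 with the slide as a block (1072 at an unadjusted p under 0.05), 0 on the shared slide alone (698) and 0 at an adjusted p under 0.01 (3132). The 1072 and the 698 are no more than chance alone would give. The random slide block took a correlation of -0.0581 between arrays of a slide. Its higher counts therefore do not show that differences hold within slides. Genes shared by both comparisons with normal (2877) numbered 1046 with normexp, 9750 without the filter, and 1667 to 3912 with each array left out (1740 without normal 1, 1667 without normal 2). Array weights ranged from 0.229 for IR-3W 3 to 4.24 for normal 2, with 3.08 for IR-3W 4, so weighted fits lean on few arrays.

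The replicate numbers did not pair the samples. Same-numbered samples correlated in their deviations from the group means at -0.206 to 0.0774 (10 pairs, median -0.0116), other pairs at -0.325 to 0.381 (44 pairs), and 0 of 11 samples correlated best with its own number. With the replicate number as a block the gene count was 1608 for IR-3W against normal, 2294 for IR-7W against normal and 0 in limma between the carcinoma groups (2067 at an unadjusted p under 0.05), and lists numbered 9, 9 and 10.

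Lists passing camera for IR-3W against normal (7) numbered 4 with the deposited values, 4 without the filter, 4 with the filter on all arrays, 1 with an estimated correlation, 1 with fry, and 4 to 8 with each array left out (4 without IR-3W 2). For IR-7W against normal (2) they numbered 7 with normexp, 5 with the deposited values, 4 without the filter, 4 with the filter on all arrays, 4 with the mean of a gene's probes, 1 with an estimated correlation, 4 with fry, and 2 to 7 with each array left out (7 without normal 3 or IR-7W 4, 6 without IR-7W 6, and 4 without normal 2, IR-7W 1 or IR-7W 2). Between the carcinoma groups (11) they numbered 7 with normexp, 7 with quantile scaling, 7 with median scaling, 6 with the deposited values, 7 with the filter on all arrays, 7 with outlier spots kept, 7 with the mean of a gene's probes, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 1 with fry, and 6 to 11 with each array left out (6 without IR-3W 1 or IR-7W 1, and 7 without IR-3W 2 or IR-7W 6). Score tests passing numbered 4 with normexp, and 0 by exact permutation as reported (5 at an unadjusted p under 0.05).

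Directions turned as follows, for genes against 0 and for lists by the direction that camera gave, which can differ from the sign of the mean. Esr1, Pgr and Ereg were dim on whole groups, so their values are fitted differences and not measured folds. Under normexp, between the carcinoma groups, Esr1 gave 0.62, Flvcr2 0.33, Foxa1 0.46, Gdpd1 0.079, Magix 0.61, Otc 0.73 and Tgfa -0.10, and the mean of cell cycle genes was 0.33 and of hypoxia and glycolysis genes 0.40, the first below and the second just above the shifted median of all genes. Under normexp, for IR-3W against normal, Ccne2 gave -0.026, Erbb3 -0.23, Ereg -0.22 and Pgr -0.33, and for IR-7W against normal Egf gave -0.25, Erbb3 -0.070, Ereg -0.0071, Esr1 -1.02, Spry4 -0.33 and Tnfrsf19 -0.85. Against the shifted median of all genes, the direction was kept for Flvcr2, Gdpd1, Ccne2 and, for IR-7W, Egf, Erbb3, Ereg and Spry4, and turned for the other genes. For IR-3W against normal, Ash1l gave -0.39 with quantile scaling and -0.22 with the filter on all arrays, where another probe was used, Ereg gave -0.79 with the deposited values, and array weights gave -0.31 for Erbb3 and -0.074 for Pgr. Array weights gave -0.034 for Erbb2 (IR-7W against normal), -0.20 for Egf and 0.25 for Nrg1 (between the carcinoma groups), and the mean of a gene's probes gave -0.021 for Prkdc (IR-7W against normal). With the slide as a block and on the shared slide alone, Egf gave -0.53, Egfr 0.12, Nrg1 0.53, Nrg2 0.077, cell cycle genes -0.28, endothelial markers 0.031 (below other genes) and interferon response genes 0.12.

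With each array left out, for IR-3W against normal, Egf ranged from -0.48 (without IR-3W 3) to 0.63, Erbb3 from -0.079 (without normal 3) to 0.53, Ereg from -0.44 (without IR-3W 1) to 1.16, Hbegf from -0.83 to 0.12 (without IR-3W 1), Nrg1 from -0.52 (without IR-3W 2) to 1.66 and Prlr from -1.13 to 0.11 (without IR-3W 2). For IR-7W against normal, Egf ranged from -0.066 (without normal 2) to 0.36 and Erbb2 from -0.12 (without normal 3) to 0.21. Between the carcinoma groups, Egf ranged from -0.58 (without IR-3W 3) to 0.53, Nrg1 from -1.61 to 0.57 (without IR-3W 3), Nrg2 from -0.71 to 0.19 (without IR-3W 1), Tgfa from -0.42 (without IR-3W 2) to 0.57 and cell cycle genes from -0.071 (without IR-3W 2) to 0.61.

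Over the settings other than left-out arrays, the adjusted p of lists for IR-3W against normal ranged from 9.42e-22 to 0.0225 for adipocyte markers, 1.13e-12 to 0.79 for matrix genes, 1.22e-07 to 0.993 for cell cycle genes, 2.13e-06 to 0.993 for hypoxia genes, 0.00127 to 0.79 for interferon genes, 0.00235 to 0.79 for endothelial and 0.000644 to 0.79 for T and NK cell markers. For IR-7W against normal it ranged from 8.16e-13 to 0.04 for adipocyte and 2.63e-06 to 0.858 for endothelial markers. Between the carcinoma groups it ranged from 1.3e-30 to 0.1 for matrix genes, 2.47e-11 to 0.397 for luminal, 4.51e-05 to 0.806 for endothelial, 4.19e-06 to 0.663 for macrophage, 0.00158 to 0.663 for myoepithelial and 4.52e-06 to 0.663 for red blood cell markers. It was 4.68e-05 to 0.932 for hypoxia genes, 0.0121 to 0.855 for hormone receptors, 0.0039 to 0.663 for ErbB receptors, 0.000981 to 0.845 for interferon and 0.00178 to 0.977 for cell cycle genes. For IR-3W against normal Psmb8 had 0.00146 to 0.0873 and Rsad2 0.000256 to 0.172, Car9 3.08e-05 to 0.165, Wnt5a 2.39e-06 to 0.231 and Cnn1 0.0055 to 0.0757. For IR-7W against normal Prlr had 0.000407 to 0.0433, Pgr 0.0012 to 0.97, Cited1 5.43e-05 to 0.0616, Xrcc5 6.06e-05 to 0.291, Rad50 6.93e-05 to 0.911, Msx2 0.000356 to 0.102 and Erbb3 0.0145 to 0.841. Cldn3, Cnn1 and Igfbp4 reached from 0.00309, 0.00681 and 0.00371 to 1 between the carcinoma groups, and Aspn from 0.00209 to 0.106 and from 0.00493 to 0.133 for IR-3W and IR-7W against normal. Fgfbp1 had 0.00176 to 1 between the carcinoma groups.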

Other observations

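The test of fat-cell loss was chosen only after the result was seen. Nerve, repair and early response genes had single calls in the IR-7W carcinomas without list shifts. Egr2, an immediate early and myelin transcription factor, rose by 2.88 ± 0.33 on the log2 scale (adjusted p = 9.16e-05 in limma; higher in 6 of 6 carcinomas), while Cadm3, an adhesion molecule of axons (well above background on 5 of 6 IR-7W arrays), fell by 2.88 ± 0.46 (-1.74 under normexp). Xrcc5, the Ku80 subunit of DNA end joining, had 1.57 ± 0.26 and Rad50, a double-strand break sensor (well above background on 1 of 3 normal arrays), had 1.44 ± 0.27, but under normexp neither passed (0.27, adjusted p = 0.291, and 0.034, adjusted p = 0.911), where the median of all genes moved to -0.55. Parp1, which marks DNA breaks with ADP-ribose, fell by 1.07 ± 0.17. Prkdc, the catalytic kinase of end joining, had 1.57 ± 0.29 (0.66 under normexp), but its other probe had -1.61. Fas, a death receptor induced by p53, stood at -1.04, a call lost without normal 1 (adjusted p = 0.11) or normal 3 (0.093), and Ephx1, a detoxifying hydrolase, at -1.14, lost without normal 1 (0.116) or normal 2 (0.0762).

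Lists on these themes did not pass camera in any of the 3 comparisons (adjusted p for IR-3W against normal, IR-7W against normal and IR-3W against IR-7W). DNA damage repair genes (26) had 0.636, 0.944 and 0.418, with 3 up and 2 down, 4 up and 2 down, and 0 in limma (4 and 2, 4 and 2, and 0 adjusted over the list alone; 0 at an unadjusted p under 0.05 in the last). The p53 targets (19) had 0.989, 0.6 and 0.293, with 1 up and 1 down, 3 up and 2 down, and 0 in limma, as when adjusted over the list alone (1 at an unadjusted p under 0.05 in the last). Immediate early genes (20) had 0.981, 0.944 and 0.781, with 2 up and 1 down, 3 up and 1 down, and 0 in limma, as when adjusted over the list alone (4 at an unadjusted p under 0.05 in the last), and for IR-7W a median of -0.07 and a mean of 0.06. Wnt targets (10) had 0.981, 0.336 and 0.0532, with 1 down, 1 up and 1 down, and 0 in limma (1 down, 1 up and 1 down, and 1 down adjusted over the list alone; 2 at an unadjusted p under 0.05 in the last).

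Markers of other tissues were scored to see what the samples held. Nerve and Schwann cell markers (10) had 0.344, 0.187 and 0.495, with 2, 3 and 0 genes lower in limma (2, 3 and 1 adjusted over the list alone; 3 at an unadjusted p under 0.05 in the last). MHC class II genes (11), of antigen-presenting cells, had 0.776, 0.944 and 0.639, with 0, 1 and 0 genes higher in limma, as when adjusted over the list alone (0 and 1 at an unadjusted p under 0.05 in the first and last). Mast cell markers (10) had 0.636, 0.944 and 0.203, with 0, 1 and 0 lower in limma, as when adjusted over the list alone (1 and 0 at an unadjusted p under 0.05 in the first and last), and their score ranged from -2.73 in IR-7W 3 to 2.95 in IR-7W 4. Skeletal muscle markers (15) had 0.981, 0.944 and 0.996, with 0, 1 and 0 lower in limma (0 adjusted over the list alone; 2, 2 and 1 at an unadjusted p under 0.05). Their mean and median differed in sign for IR-7W against normal (-0.04 and 0.23) and between the carcinoma groups (-0.04 and 0.15), their camera direction was upward for IR-3W (median -0.17), and their score was highest in IR-7W 6 (2.79) and IR-3W 1 (2.47). Skin keratinocyte markers, with 4 genes tested and so no list test, had 0 limma calls in each comparison (1, 3 and 1 at an unadjusted p under 0.05; 0, then 2 up and 1 down, then 0 adjusted over the list alone). Milk protein genes scored 3.04 in IR-3W 3 and -2.39 to 1.47 in the other samples.

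The genes lower in the IR-7W carcinomas could be a loss of fat cells with all other cell types kept in proportion. That was argued against, because luminal and endothelial markers moved apart by 2.28 against normal tissue (luminal minus endothelial score 0.94 ± 0.52, SD, n = 6, against -1.35 ± 0.16, n = 3; exact two-sided permutation p = 0.0119, the smallest possible over 84 splits). The fall of the endothelial markers was already known when this test was chosen. A fat-cell loss joined with a change in vessels stays open. So does the scan, which cannot be told apart from the group, and so does age, since the labels differ on the age of the normal tissue. Diet stays open too, since it is given for the carcinoma groups alone.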
